A study of Tribolium castaneum with 10 samples.

How the data were processed

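RNA of whole virgin adults of the red flour beetle, Tribolium castaneum, was measured on a NimbleGen expression array with 60-base probes and a single dye, Cy3. Each sample pooled 20 beetles of 1 sex. The labels give 4 biological samples for each sex, and sample 3 of each sex was hybridised to 2 arrays, which makes 10 arrays. The arrays within a pair are technical repeats of 1 sample. Beetles were kept in groups of a single sex, and the labels describe the biological samples as separate pools without naming a shared cage or batch.

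The scanner files hold the raw intensity of each spot, extracted with NimbleScan 2.4.31 per the file headers. Each array has 389307 spots, of which 54231 are random-sequence control spots and 335076 are spots of 167538 genomic probes, each printed as 2 spots. A second kind of deposited file gives a mean intensity for each exon. In all 114446 exon and block entries of every array, that mean was equal to the mean of the raw spots within 1 intensity unit, so these files served as the source of the gene, chromosome, start and end of each exon. The authors' table of the whole series holds log2 values for 57223 exons and regions, made with RMA per the submitters' processing notes. Its column medians lay between 11.07 and 11.11, and each column correlated with the exon values computed here from the same array at Pearson r from 0.985 to 0.988 across exons, which are not independent replicates. The log2 scale and the absence of gene centring follow from these values, and the background step and probe grouping behind that table are not given in the sources used here.

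The main values were computed from the raw intensities. Background was corrected with normexp and an offset of 50 on all spots, the random spots were then left out, the arrays were quantile-normalized, and log2 values of the 2 spots of a probe were averaged. Probes of a gene, 6 in the median gene, were summarised by median polish. The arrays of sample 3 were averaged before any fit, which left 4 female and 4 male samples. Sex differences are female minus male on the log2 scale, from limma 3.58.1 (lmFit and eBayes) in R 4.3.3, fitted to 16434 features together, with Benjamini-Hochberg adjustment and a threshold of 0.05. These features are 16130 predicted genes and 304 expressed regions outside the gene models. No filter on dim features was applied. A feature is called above random spots in a sample where its value exceeds the 95th percentile of that array's random spots, carried to the normalized scale.

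Chromosomes and coordinates are those of the array's annotation, and its genome build is not given in the sources used here. The X and autosomes 2 to 10 are named there, and 3555 genes have no chromosome. X-linked and autosomal genes were compared with Fisher's exact test, two-sided. The median of X-linked genes minus the median of autosomal genes was taken per sample and compared between the sexes with an exact permutation test, two-sided. Exon usage was tested with limma's diffSplice on exon means of the probe values, with Simes p-values per gene. Intervals on shares are exact binomial intervals at 95%. For arrays, the number of samples limits the precision.

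The main design and its alternatives were fixed before the data were examined, as were the rule for named genes and 18 gene lists. The alternatives changed the background correction, the normalization, the probe summary, the source of the values, a filter on dim features, the treatment of technical repeats, the variance model and the threshold, and left out each sample in turn. Others were added after seeing the data: the processing date as a block, the omission of samples 1 and 2 of the females or of both sexes, an exon test that uses each exon's own spread, and the median of per-gene sex differences on the X minus that on the autosomes.

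Gene identifiers of the array were matched to a reference table of another assembly, icTriCast1.1, through its synonyms only. This named 56 features, of which 41 have a symbol other than a placeholder. The fixed lists are patterns of names and description words, and none of these patterns matched a symbol. The symbols do include hexamerins, cytochromes P450 and subunits of the respiratory chain, but as abbreviations that the patterns do not match. The list tests, with preset or estimated correlation, were therefore not run, nor was the alternative that leaves out the reproductive lists. By the rule, named genes past the threshold are given where the samples of the sexes did not overlap, up to 10 in each direction, with at most 2 unnamed identifiers and 2 regions in each direction. Genes named doublesex, transformer, vasa or vitellogenin were to be given in any case, and none was among the symbols.

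The fits were tested on simulated data. For the sex difference over 16434 features, limma recovered 17.9% of 67 features changed 1.5-fold, 50.8% of 67 changed 2-fold and 90.9% of 66 changed 4-fold, with 3.64% of its calls false. For exon usage over 11382 genes, 2.97% of diffSplice's calls were false when all exons of a gene had the same spread. When each exon kept its own spread, 41.7% of its calls were false, or 25.2% with moderated spreads. The exon test with each exon's own spread gave 7.02% and 11.1% false calls in the same simulations, but recovered less. In the first of these it recovered 0%, 10.45% and 69.7% of genes with 1 exon changed 1.5-fold, 2-fold and 4-fold. For diffSplice these shares were 5.97%, 49.25% and 92.42%. All simulations drew noise independently for each feature, with the same spread in both sexes. In the data the median SD of a gene was 0.31 among females and 0.18 among males. A split that mixed the sexes had 1143 genes under an unadjusted limma p of 0.00559, where 90.2 are expected by chance. The simulated rates of false calls therefore need not hold for these samples.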

Results

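The series surveyed transcript levels in females and males of Tribolium castaneum strain GA-2. Whole virgin beetles aged 48 to 168 h, reared at 29 °C in flour with 5% yeast, were pooled by 20, and 4 female and 4 male samples were compared. The median raw intensity of genomic spots lay between 2182 and 3396 on the 10 arrays, and that of random spots between 145 and 279.9. Between 87.3% and 99.6% of genes were above random spots on an array. Samples correlated across genes at Pearson r from 0.862 to 0.980 among females, from 0.952 to 0.994 among males and from 0.795 to 0.944 between the sexes. The median SD of a gene was 0.31 among females and 0.18 among males on the log2 scale (n = 4 each), while technical repeats correlated at 0.992 in females and 0.998 in males. Header dates put females 1, 2 and 4 with males 1, 2 and 3 on 1 date, and female 3 and male 4 each on a date of its own.

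The first comparison asked which genes differ between the sexes. Of 16130 genes, 1836 (11.4%) were sex-biased, 578 with higher signal in females and 1258 with higher signal in males. Male-biased genes differed more, with a median of 3.75-fold against 1.62-fold for female-biased genes. A difference of at least 4-fold was present in 585 male-biased and 35 female-biased genes. Over all genes, called or not, the samples of the sexes did not overlap in 1641 genes higher in females and 1631 higher in males, 20.3% of genes, where chance alone gives 2.86%. Of these, 1083 of the genes higher in females and 375 of those higher in males were not called. In 22 male-biased genes all male samples and no female sample were above random spots, and 0 female-biased genes had the opposite pattern. Male 4 had 99.6% of genes above random spots, and the arrays of female 3 had 99.4% and 99.0%. Few genes could thus be below random spots throughout a sex, so these counts do not compare the sexes. Unadjusted limma p-values under 0.05 numbered 2008 with higher female and 1714 with higher male signal. Over all genes the median difference was 0.17 (log2, female minus male), against 0.08 with cyclic loess and 0.24 with median scaling.

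**Figure D1:**
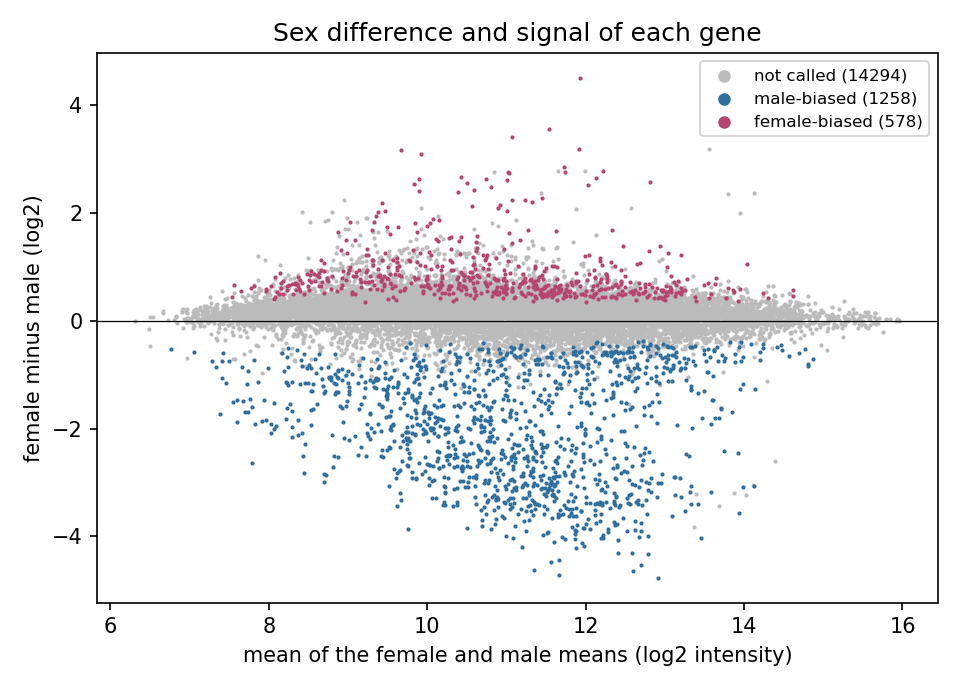
Each point is a gene, with the mean of its female and male means (log2 intensity) on the horizontal axis and the female minus male difference (log2) on the vertical axis; the 1258 male-biased genes extend further from 0 than most of the 578 female-biased genes.

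Among genes with a symbol, slmb, which encodes an F-box protein of a ubiquitin ligase, was the single one past the threshold. Its signal on chromosome 2 (5728741 to 5731867) was 13.23 ± 0.13 in females and 12.77 ± 0.10 in males (log2, SD, n = 4), a difference of 0.46 (SE 0.11, limma adjusted p = 0.0326). That call was lost in every fit that left out 1 sample except the one without female 3, with limma adjusted p from 0.0714 to 0.0996, and over all alternatives the adjusted p ran from 0.000164 to 0.819. P121, chosen after its value was seen, differed by -0.49 (limma unadjusted p = 0.00561) and missed the threshold after adjustment. The other symbols, which include hexamerins, cytochromes P450 and subunits of the respiratory chain, did not pass.

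The largest differences among called genes whose samples did not overlap between the sexes belonged to genes without a symbol. The largest of all female-biased genes, at 22.7-fold, is not among them, since its samples overlapped. GLEAN_15344 (chromosome 6, 198235 to 199032) was 13.31 ± 0.50 in females and 9.76 ± 1.41 in males, a difference of 3.56 (SE 0.64, limma adjusted p = 0.00705). GLEAN_06658 (chromosome 8, 13534281 to 13535587) was 3.41 higher in females (SE 0.49, limma adjusted p = 0.00208). GLEAN_07207 (chromosome 4, 8591782 to 8592525) was 10.53 ± 2.24 in females and 15.29 ± 0.18 in males, a difference of -4.76 (SE 0.95, limma adjusted p = 0.0123). GLEAN_07979 (chromosome 4, 3940665 to 3941517) differed by -4.71 (SE 0.82, limma adjusted p = 0.00571) and was above random spots in 3 of the 4 female samples. Both male-biased genes were higher in females 1 and 2 than in females 3 and 4, for GLEAN_07207 at 12.38 and 12.54 against 8.79 and 8.39. Without females 1 and 2 the difference in GLEAN_07207 was -6.70; GLEAN_07979 was above random spots in 1 of the 2 remaining females. Without female 1, 2 or 4 that of GLEAN_07207 was -5.38, -5.43 and -4.05, and without female 2 or 4 that of GLEAN_07979 was -5.33 and -4.10. Within the shared date they were -4.10 and -4.18. Without females 1 and 2 the call of GLEAN_15344 was lost (limma adjusted p = 0.0876, from 0.00117 to 0.0876 over its alternatives). Without samples 1 and 2 of both sexes that of GLEAN_06658 was lost (limma adjusted p = 0.183, from 0.000151 to 0.183).

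Male-limited transcripts were not at one level in the females. For each female sample, genes were taken whose male mean was at least 12 (log2) and which lay at least 4 below it in another female sample. The median of 231 such genes lay at -2.64 relative to the male mean (log2) in female 1 and at -2.59 in female 2. It lay at -3.93 in female 3 (225 genes) and at -5.13 in female 4 (114 genes). Genes with a female mean of at least 12 that lay at least 3 below it in another male sample had medians of -2.48, -1.73, -4.28 and -2.55 in males 1, 2, 3 and 4, over 26, 26, 11 and 26 genes. Without females 1 and 2, 144 female-biased and 1021 male-biased genes were called. Without samples 1 and 2 of both sexes, which leaves 2 against 2, these counts were 3 and 512.

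The number of female-biased genes depended on single samples and on the scaling. With median scaling it was 347. With the replicate number as a block it was 168, although no label says that the numbers pair the samples. It was 1357 without female 3, 332 without female 1, 268 without female 4, and 298, 260, 228 and 333 without males 1, 2, 3 and 4. Without female 3 the total rose to 2766. With the date as a block, which rests on females 1, 2 and 4 against males 1, 2 and 3, 1126 female-biased and 1366 male-biased genes were called, and array weights gave 4551 and 2105. The split with females 1 and 3 and males 1 and 4 on one side had 1072 genes in its larger direction under the unadjusted p of the last call between the sexes (0.00559).

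Sex bias was then compared between the X, of which females carry a pair and males a single copy, and the autosomes. Whole beetles were used, so gene dose cannot be told apart here from differences between the sexes in tissue content. Female-biased genes made up 10.7% of 561 X-linked genes and 2.98% of 12014 autosomal genes, an odds ratio of 3.90 (95% interval 2.87 to 5.22, Fisher's exact p = 5.05e-16). Male-biased genes made up 4.46% of X-linked and 8.32% of autosomal genes, an odds ratio of 0.514 (0.328 to 0.772, Fisher's exact p = 0.000643). Among female-biased genes at least 2-fold apart the difference between X and autosomes was not past the threshold, with an odds ratio of 1.12 (Fisher's exact p = 0.806); the median X-linked female-biased gene differed 1.58-fold. Without samples 1 and 2 of both sexes 3 female-biased genes were left and X-linked female bias was not past the threshold (Fisher's exact p = 0.128). The odds ratio of X-linked female bias was 2.57 with array weights and 2.11 with the replicate number as a block (Fisher's exact p = 0.0261). Within the shared date the odds ratios were 3.26 for female and 0.535 for male bias.

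Each chromosome was set against the other autosomes in a family of 20 tests. Besides the X, chromosome 5 had more female-biased genes, 4.14% with an odds ratio of 1.51 (Fisher's exact test, adjusted p = 0.0131). Chromosome 8 had more male-biased genes, 10.4% with an odds ratio of 1.33 (Fisher's exact test, adjusted p = 0.0131). Fisher's test and the binomial intervals treat genes as independent, but 50 adjacent pairs were both female-biased, where permuting calls gave a mean of 17.1. For male-biased genes these were 188 and 85.7. The p-values of single chromosomes, the X included, may thus be too small, and chromosomes 5 and 8 were not tested in the alternatives. Of the 3555 genes without a chromosome, 4.50% were female-biased and 6.55% male-biased.

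**Figure D2:**
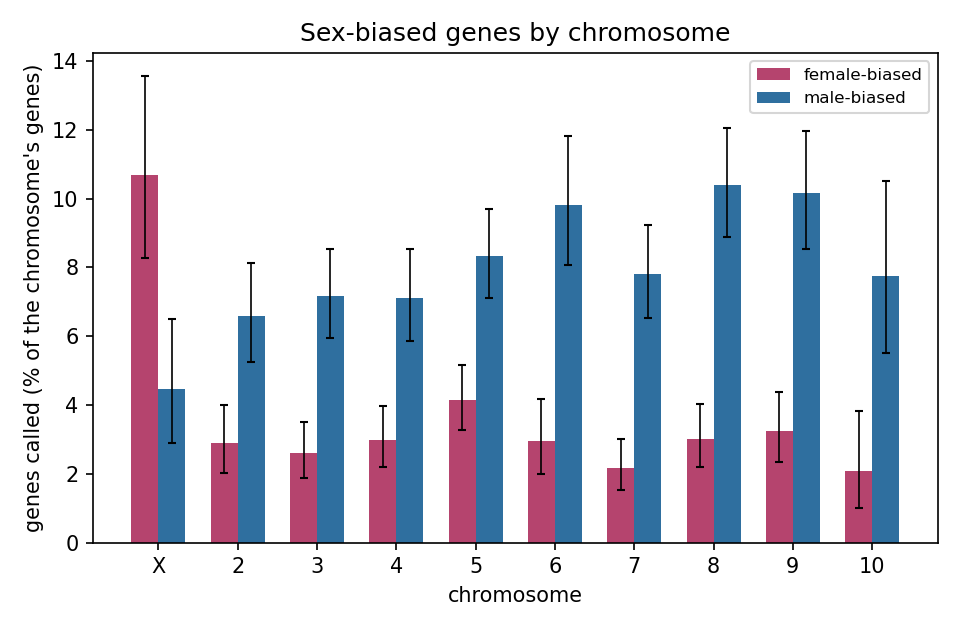
Bars give the percentage of each chromosome's genes that were female-biased or male-biased, with exact 95% binomial intervals; the X has the highest female-biased share (10.7%) and the lowest male-biased share (4.46%).

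The median level of X-linked genes relative to that of autosomal genes was higher in females than in males. This X minus autosome difference was 0.31 ± 0.05 in females and 0.07 ± 0.05 in males (log2, SD, n = 4), a difference between the sexes of 0.24, or 1.18-fold (exact permutation p = 0.0286, the smallest that 4 against 4 samples allow). Taken gene by gene, a measure added after seeing the data, the median female minus male difference was 0.26 in X-linked and 0.15 in autosomal genes. They were 0.11 apart, or 1.08-fold, which did not pass the threshold (exact permutation p = 0.114), although it did without female 2, female 4 or male 4 (exact permutation p = 0.0286 in each). The female samples lay at 0.32, 0.36, 0.25 and 0.32 and the male samples at 0.08, 0.12, 0.09 and 0.00. Over all genes the difference was above 0 in every sample. Within 6 ranges of signal its male mean lay from -0.17 to -0.08 and its female mean from 0.01 to 0.22. The ranges were set on each gene's mean over both sexes, which places X-linked and autosomal genes near the same mean. Opposite signs in the sexes therefore follow largely from the ranges and do not show a male X below the autosomes. Females were higher than males in each range, by 0.12 to 0.31 (exact permutation p = 0.0286 in each), and gene by gene by 0.04 to 0.19, which was not tested within ranges. Within the shared date the difference of medians was 0.24 and that taken gene by gene 0.11, where 3 against 3 samples allow no p under 0.1.

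**Figure D3:**
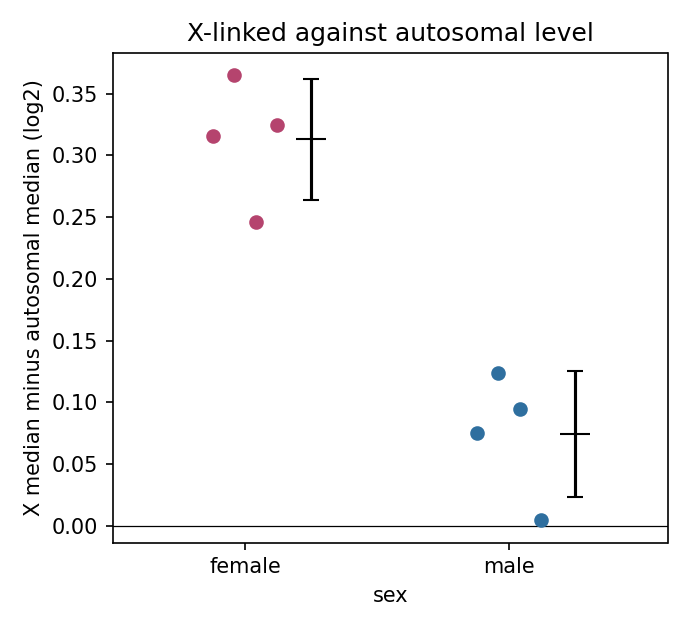
Points are samples, and the vertical axis is the median of X-linked genes minus the median of autosomal genes (log2); horizontal marks with bars are the mean ± SD of the 4 samples of a sex, and every female sample lies above every male sample.

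Expressed regions outside the gene models were called less often than genes. Of 304 regions, 4 were called, all higher in females, against 11.4% of genes (odds ratio 0.104, Fisher's exact p = 3.73e-11). Fisher's test treats regions as independent, but their mean level varied with an SD of 0.52 among females and 0.32 among males, so regions moved together. Whether a difference is as easily called in regions as in genes was not tested. The region on chromosome 7 from 12837158 to 12837299 was 12.88 ± 0.11 in females and 11.84 ± 0.15 in males, a difference of 1.04 (SE 0.12, limma adjusted p = 0.000589), and its call was lost without samples 1 and 2 of both sexes (limma adjusted p = 0.153, from 6.85e-06 to 0.153 over its alternatives). The region on chromosome 3 from 6132850 to 6133173 differed by 0.70 (SE 0.17, limma adjusted p = 0.0316), and its call was lost without female 1, female 4, male 1, male 2 or male 3, with adjusted p from 0.0763 to 0.105 (from 0.000609 to 0.473 over all its alternatives). The remaining calls, outside the rule for named features and chosen after their values were seen, lay on chromosome 5 from 3800219 to 3800360, with a single probe and a difference of 0.58, and from 12332526 to 12332758, with a difference of 0.54. The call of the single-probe region was lost in every fit that left out 1 sample except the one without female 3. That of the other region on chromosome 5 was lost with median scaling (limma adjusted p = 0.118) and with the replicate number as a block (0.116). It was also lost without females 1 and 2 (0.0571) and without samples 1 and 2 of both sexes (0.573). Over its alternatives the limma adjusted p ran from 0.000243 to 0.573. Of all regions, 270 were higher in females, and at an unadjusted limma p under 0.05 there were 22 higher in females and 1 higher in males. In a split of the samples with females 1 and 3 and males 1 and 4 on one side, 138 regions were under the unadjusted p of the last call between the sexes (0.00559). The mean level of all regions was 12.35 ± 0.52 in females and 12.04 ± 0.32 in males (exact permutation p = 0.371, n = 4). The count was 12 both without female 3 and with the date as a block, and 2 in each of the fits without female 1, female 4, male 1, male 2 or male 3.

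Exons that differed between the sexes apart from their gene were found mainly in male-biased genes. Of 11382 genes with several exons, 390 were called, among them 230 of 909 male-biased genes (25.3%), 12 of 427 female-biased genes (2.81%) and 148 of 10046 genes with no call (1.47%). Sex-biased genes were called more often than others (odds ratio 14.8, 95% interval 11.9 to 18.4, Fisher's exact p = 1.75e-130). The gene call and the exon call rest on the same probes, so this association is not independent of the size of a gene's difference. GLEAN_02408 was not called as a whole. Its exon on chromosome 3 from 30676018 to 30676713 was 8.88 ± 1.08 in females and 12.82 ± 0.13 in males, which put it at -3.89 relative to the gene's other exons. This exon was above random spots in 7 of 8 samples. The diffSplice adjusted p of the gene (Simes) was 1.77e-26, which rests on 1 spread for all its exons and not on that of this exon. In GLEAN_10347, which has no chromosome, the exon from 161762 to 161959 was at -3.31 (diffSplice adjusted p of the gene, Simes, 4.74e-25). Both were chosen by adjusted p after the values were seen, since no gene with a symbol was called, and both exons were relatively higher in males. The deciding exon was relatively higher in males in 67 of the 230 male-biased genes, in 10 of the 12 female-biased genes and in 113 of the 148 genes with no call. In most called genes of either bias it was thus relatively higher in the sex with the lower signal of the gene, and it was not above random spots in every sample in 31.3% of the male-biased and 75% of the female-biased ones.

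The diffSplice count rests on 1 spread for all exons of a gene. A split of the 8 samples that mixed the sexes, with females 1 and 3 and males 1 and 4 on one side, gave 395 calls, 3 of them in the 390 genes. With each exon's own spread, a test added after diffSplice gave false calls on simulated data, 482 genes were called, 337 of them in common, and 31.4% of male-biased genes against 1.75% of genes with no call were among them. The adjusted p of GLEAN_02408 was then 0.00896 and that of GLEAN_10347 was 0.000657. With the date as a block diffSplice called 432 genes, and without samples 1 and 2 of both sexes 138.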

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

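The tests of exchanged labels, genomic DNA, date, first or last exons in male-biased genes, exon usage with each exon's own spread, and splits at a fixed p were chosen only after the results had been seen, as was the examination of hexamerins. In 32 groups of 4 samples, 4 had a sample far from the others, where chance alone gives about 1 in 20. The groups include the hexamerins and features chosen for their sex difference, and they share samples, so their number cannot be weighed against that rate. The scanner's quality score was 1.832 in female 4 against 0.263 to 0.312 in the other females. The mean score of male 3 was 0.226 against 0.438 to 0.446 in the other males. GLEAN_07207 was at 15.56 in male 4 against 15.18 to 15.23 in the other males. HEX2, a hexamerin, a class of insect storage proteins, was at 14.69 in female 3 against 9.29 to 9.98 in the other females.

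Male-limited transcripts stood at about the same distance below the male mean in females 1 and 2, with medians of -2.64 and -2.59 (log2) and an interquartile range over genes of 0.58 and 0.27 log2 units, against 0.17 to 0.30 in single male samples set against the other males. Female-limited genes lay at -2.48, -1.73 and -2.55 relative to the female mean in males 1, 2 and 4 (26 genes, interquartile ranges 0.94, 0.40 and 0.59), with slopes on that mean of 0.11 (SE 0.22), 0.07 (SE 0.16) and 0.07 (SE 0.14). A constant array background would make the distance grow with the male level, with a slope near -1, and the slopes were 0.39 (SE 0.03) and 0.21 (SE 0.03), which argues against it in these females. Exchanged labels would put the genes at the male level, and the nearer sample lay at -2.59. Male RNA at 1 share in these females may account for the pattern, since the slopes stayed within the bound of 0.5 set beforehand. They are not 0, the slope that 1 share alone would give, so the bound does not show a single share. Such RNA would make the folds between the sexes smaller than in unmixed samples. Female RNA in males would lower male-limited genes most in male 2. Relative to the other males, these 231 genes lay at -0.11, 0.04, -0.003 and 0.09 in males 1, 2, 3 and 4, so male 2 showed no such lowering. How RNA of the other sex could have entered, and whether these samples differed in biology such as age, was not tested.

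Dim probes were brightest in female 3 and male 4, where they lay 1.13 and 1.55 log2 units above random spots against 0.37 to 0.72 elsewhere, while regions outside genes were brightest in female 3 and, among males, in male 4. Genomic DNA could give such a signal, and the X to autosome ratio of dim signal in male 4 was 0.805 of that in female 3, where DNA as the whole source would give a value near 0.5. The spread of that ratio between samples was 0.15, so the bound of 0.7 was not passed by more than the spread and DNA stays open. Processing date cannot be told apart from the samples, since each of these samples has a date of its own; female 1, of the shared date, had a mean region level 0.17 above that of male 4, which is within the spread of that date's samples. No biological explanation was tested.

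Exon usage calls were concentrated in male-biased genes. Exons near background that do not follow their gene could add to this, and the deciding exon was not above random spots in every sample in 31.3% of these genes, between the bounds of 20% and 50% set beforehand, against 20.3% in genes without a call and 75% in the 12 female-biased genes, so this stays open. Gene models that join neighbouring transcripts may contribute, since in male-biased genes with at least 3 exons the deciding exon was the first or last 1.89 times as often as a random exon (130 of 195 genes, permutation p = 1e-05, the smallest that the resamples can give). The ratio was 1.44 in genes without a call (68 of 134), and whether these ratios differ was not tested. True alternative first or last exons give the same excess, and sex-specific transcripts of these genes remain an untested biological explanation.

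All 35 splits of the 8 samples into 4 and 4 were fitted. For sex-biased genes the real split gave 1836 and the highest other 0 after adjustment, or 1143 at the unadjusted p of the real split's last call (0.00559). No other split reached the real one, which is the strongest rank that 35 splits allow and does not by itself exclude chance. Every other split mixes the sexes, so sex differences add to the spread within its sides and lower its count. Female-biased genes, male-biased genes and regions share an adjustment with all other genes, so they were counted in each split at that unadjusted p. Male-biased genes numbered 1258 against at most 1072 genes in the larger direction of any other split, so no other of the 35 splits reached the real one. Female-biased genes numbered 578, and 2 splits reached that in their larger direction, the real one and 1 other with 1072, so chance is not excluded by this count. They are the smaller direction of the real split, and in the smaller direction the highest other split had 71, so the answer depends on which direction is compared. For regions chance is not excluded, with 4 against a highest of 138 and 3 splits as large, the real one included. For exon usage with diffSplice, 2 of the 35 splits gave as many calls, the real one with 390 and another with 395, so chance is not excluded there either. The highest other split was in each of these counts the one with females 1 and 3 and males 1 and 4 on one side, which points to a structure of the samples, since it parts the 4 samples whose dim probes lay highest above random spots from the rest. Within the shared date, 1126 female-biased genes and 12 regions were called. With each exon's own spread the real split gave 482 genes and the highest other 0, both after adjustment. The gene fit also gave 0 after adjustment in every other split, although 1 of them had 1143 genes at the unadjusted p. No count at an unadjusted p was made for this exon test, so its 0 does not exclude chance.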

How the results depend on the processing

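The settings with date as a block, with samples 1 and 2 left out, with each exon's own spread and with per-gene X differences were chosen after seeing the data. The X minus autosome difference between the sexes kept its direction in every setting run, at 0.182 to 0.281 as a difference of medians, but as a median of per-gene differences it was 0.105 and not past the threshold (exact permutation p = 0.114), and X-linked male bias stayed past the threshold in every setting run, with odds ratios of 0.479 to 0.596. X-linked female bias lost the threshold at 2-fold or more (odds ratio 1.12) and without samples 1 and 2 of both sexes (10.7), where 3 female-biased genes were left, and its odds ratio was 2.11 with the replicate block and 2.57 with array weights. Sex-biased genes numbered 1164 with the replicate block, 6656 with array quality weights, 1088 at 2-fold or more, 1142 at an adjusted p under 0.01, 1165 without females 1 and 2, and 515 without samples 1 and 2 of both sexes. Female-biased genes numbered 347 with median scaling, 168 with the replicate block, 4551 with array weights, 129 at 2-fold or more, 153 at an adjusted p under 0.01, 1126 with the date block, 144 without females 1 and 2, and 3 without samples 1 and 2 of both sexes. Male-biased genes numbered 2105 with array weights and 512 without samples 1 and 2 of both sexes. Regions numbered 1 with median scaling, the replicate block, 2-fold or more, or an adjusted p under 0.01, 7 with an intensity trend, 54 with array weights, 12 with the date block, and 0 without samples 1 and 2 of both sexes. Exon usage gave 138 genes in that last setting. Leaving out each sample in turn gave 1286 to 2766 sex-biased genes, 228 to 1357 female-biased genes and 2 to 12 regions. Array weights ran from 0.0999 for female 3 to 6.14 for male 2, and female 4, with the scanner quality score of 1.832, had 5.43. Samples of the same number deviated from their sex's mean with correlations of -0.08, 0.55, -0.51 and -0.55 across genes, and not every sample correlated best with its own number. These values do not show that the numbers pair the samples. They cannot exclude a batch shared by number, since each rests on 1 sample of each sex and any other difference between samples enters it. For slmb, 4 genes without a symbol, 4 regions and 2 exons named in the text, 218 of 266 alternatives kept the direction and the side of the threshold, 48 lost the threshold and 0 reversed. Arrays kept apart, the variance models, array weights and thresholds give no X minus autosome value. The patterns of the fixed gene lists matched no symbol, so the lists were not tested. The stricter thresholds call fewer genes by construction, and the cause of the other changes was not tested. Signal over background limits dim genes, and 13852 of 16130 genes were above random spots in all 8 samples.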

Other observations

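The tests of adjacency and of single-exon genes were fixed before their results were seen, and that of unplaced genes after. Of 3 hexamerins, storage proteins of the insect fat body, none passed the test between the sexes (limma adjusted p = 0.843 for HEX2, 0.598 for HEX1B and 0.385 for HEX4). HEX2 was 10.93 ± 2.52 in females and 10.58 ± 0.47 in males (log2, SD, n = 4), HEX1B was 13.65 ± 1.16 and 13.18 ± 0.39, and HEX4 was 9.50 ± 0.59 and 8.94 ± 0.49. In female 3 HEX1B was at 15.33 against 12.68 to 13.37 in the other females. Of the respiratory chain, SdhB was 14.26 ± 0.25 in females and 14.30 ± 0.05 in males, and ATPsynbeta was 15.09 ± 0.19 and 14.97 ± 0.09. These genes were chosen after their values were seen.

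Sex-biased genes may lie in clusters along the chromosomes. Among 12575 placed genes, 188 adjacent pairs were both male-biased, where permuting calls within chromosomes gave a mean of 85.7 and at most 122. For female-biased genes there were 50 such pairs against a mean of 17.1 and at most 35 (permutation p = 1e-05 in both, the smallest that 100000 resamples can give). Tandem copies that share probe sequence, or a transcript divided between neighbouring models, would give the same excess and were not tested.

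Male-biased genes did not have more single-exon models than genes with no call. The share was 27.7% against 29.7% (odds ratio 0.908, 95% interval 0.796 to 1.03, Fisher's exact p = 0.147).

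Part of the genes without a chromosome may be X-linked. Their female-biased share was above that of autosomal genes (odds ratio 1.53, Fisher's exact p = 1.92e-05) and their male-biased share below it (odds ratio 0.773, Fisher's exact p = 0.000526), both towards the X. Against the other autosomes, chromosome 5 had a similar odds ratio for female bias (1.51) and chromosome 2 for male bias (0.758), but neither had both. Fisher's test treats genes as independent, so these p-values may be too small and X linkage stays open. The median female minus male difference was 0.22 in these genes, between 0.15 on the autosomes and 0.26 on the X.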
